A study of Xenopus laevis with 2 samples.

How the data were processed

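Polyadenylated RNA from pooled hearts of Xenopus laevis was compared between 2 libraries, 1 from embryos injected with a control morpholino and 1 from siblings injected with a morpholino against tcf21. Per the labels, each library came from 70 to 100 hearts at stage 44 to 45 and from 1 µg of total RNA, and the embryos were kept at 16 to 23 °C. The group of each library was taken from the label that names the injected morpholino. No sample was left out.

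The authors deposited counts of whole reads for 8879 RefSeq transcripts in each library, with a gene symbol and a transcript length per row, per the file headers. These counts were not normalized. The deposited lengths, another kind of value, were in bp per the file headers and ran from 278 to 13130 with a median of 2008. The submitters' processing notes name CASAVA 1.7, Bowtie2 2.0.0.6 and SAMtools 0.1.18.0, with no role or setting. The reference build, the counting rule, the treatment of reads that match several transcripts and the use of strand are not given in the sources used here. Xenopus laevis has paired gene copies (homeologs) on its L and S subgenomes, and reads of near-identical copies could have been split or shared between rows. Values of globins, actins, keratins and other close families are uncertain for that reason, as are those of overlapping and antisense genes. The authors' own normalized values and fold changes were not used here.

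The table held 8081 symbols once homeolog and copy endings were removed, and 778 of them had more than 1 row. A name table of assembly version 10.1 was used for names only, and no coordinates were taken from it. It held 8315 of the 8879 accessions and gave another symbol for 861 of those. Both the copy ending and the homeolog ending of its symbols were removed before this comparison. This removal was corrected after results were first seen. Before the correction, the alternative with symbols from the name table lost krt8 and krt18 and gave a lower epicardium median than the main one. Symbols in the text are those of the deposited table, and where the name table differs for a named gene the text says so.

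Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.013 for the control library and 0.987 for the Tcf21-MO library. The log2 ratio of the Tcf21-MO over the control library was computed with 0.5 counts added. Each ratio has a 95% exact binomial (Clopper-Pearson) interval, conditional on the summed count of both libraries. Transcripts with at least 20 reads over both libraries entered the comparison, which left 8132. A transcript was counted as higher or lower when it differed at least 2-fold and its interval excluded a ratio of 1. No p-value was computed, because there was 1 library per group. Reads from PCR-amplified libraries without molecular identifiers are not independent molecules, so all intervals and limits cover counting error only.

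Depth was similar, with 17636925 reads in the control library and 17767221 in the Tcf21-MO library. A count of 0 allows up to 3 counts, which is 0.168 CPM (a count scaled to the effective library size) in the control and 0.171 CPM in the Tcf21-MO library. The median transcript past the floor had 1064 reads over both libraries.

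A total of 41 gene lists were fixed before the data were examined. They covered the epicardium, contractile apparatus, calcium handling, natriuretic peptides, cardiac transcription factors, endothelium, valves, matrix, matrix remodelling, adhesion, epithelial-mesenchymal transition, smooth muscle and fibroblasts. Markers of other cell types covered erythroid cells, leukocytes, thrombocytes, liver, skeletal muscle, cartilage, neural tissue, epidermis, ciliated cells, foregut and pronephros. The remaining lists held cell cycle, DNA damage, innate immune, apoptosis, signalling, metabolic, ribosomal, stress, immediate early and housekeeping genes. The row with the highest mean stood for a gene with several rows. For each list with at least 5 measured members, the median log2 ratio was computed with its 95% order-statistic interval. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3). List medians are given as log2 ratios.

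The genes named in the text were also set by a rule fixed beforehand. They were tcf21, every measured member of the epicardium list, the 15 highest and 15 lowest symbols with at least 50 reads over both libraries, the 2 highest and 2 lowest members of each list at that floor, and the 5 most abundant transcripts of each library. Members that complete a count of 5 or fewer in a list, the other homeologs of named genes, and tubb2b, stmn1 and chga were named after their values were seen. Some genes that the rule selects are not reported here.

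The procedure was tested on simulated data drawn from the real means and library sizes, with counting error only. Among 8134 simulated transcripts past the floor, 200 were changed by known amounts. Of those changed by a log2 ratio of 1.5, 99% were called in the right direction, and of those changed by a log2 ratio of 2, 100%. There were 8 calls among unchanged transcripts, and 95.5% of intervals held the true ratio.

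Alternatives covered scaling to the total count, DESeq2 1.42.0 size factors, scaling without the 50 most abundant transcripts, other added counts (5 and 0.1), other floors (none and 100 reads), other size thresholds (1.5-fold and 4-fold), an interval that had to exclude 1.5-fold, and sums over all rows of a symbol. Removal of a length trend over 20 length bins, 1 transcript per symbol, and symbols from the name table were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.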

Results

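Heart transcripts were measured by RNA sequencing in tadpoles of the frog Xenopus laevis at stage 44 to 45. Sibling embryos had been injected with a control morpholino (control-MO) or with a morpholino against tcf21 (Tcf21-MO). A morpholino is a synthetic antisense oligomer that blocks the translation or the splicing of its target. Tcf21 is a basic helix-loop-helix transcription factor of the epicardium, the cell layer that covers the heart. Each of the 2 groups was 1 library of 70 to 100 pooled hearts, with 17636925 reads for control-MO and 17767221 for Tcf21-MO. At least 1 read was counted for 8571 and 8597 of the 8879 listed transcripts, respectively. There were no replicates, so no difference has a replicate check, and the ratios compare these libraries, not the conditions. Ratios are followed by 95% counting intervals, which do not cover variation between hearts.

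The comparison asked how the cardiac transcriptome differed between hearts from embryos injected with the Tcf21 morpholino and controls. In the Tcf21-MO library, several epicardial transcripts, and matrix and innate immune transcripts as groups, were higher, and erythroid and contractile transcripts were lower. The tcf21 transcript itself had 1266 reads in the control and 3738 in the Tcf21-MO library, or 70.9 and 213 CPM. It was 3.01-fold higher (2.82 to 3.21). The labels do not say whether the morpholino blocks translation or splicing, so this level does not check the label, and no loss of Tcf21 was measured here.

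Of 8132 transcripts past the floor, 217 (211 symbols) were at least 2-fold higher and 195 (190 symbols) at least 2-fold lower in the Tcf21-MO library. The other 7720 passed neither threshold, and 84.3% of transcripts lay within 1.5-fold. The median log2 ratio was 0.00 and its standard deviation over transcripts was 0.52. Counting intervals excluded a ratio of 1 for 4734 transcripts, so the depth resolved differences far smaller than 2-fold. Of 39 gene lists with a median, 12 lay above the central 95% of random lists and 9 below it. About 2 in all would be expected if list members varied independently. Members of a list can vary together and some genes are in several lists, so these counts do not measure chance. The housekeeping list, with a median of 0.31 at percentile 97.92, was among the 12. Medians of about that size were thus not particular to any theme.

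**Figure D1:**
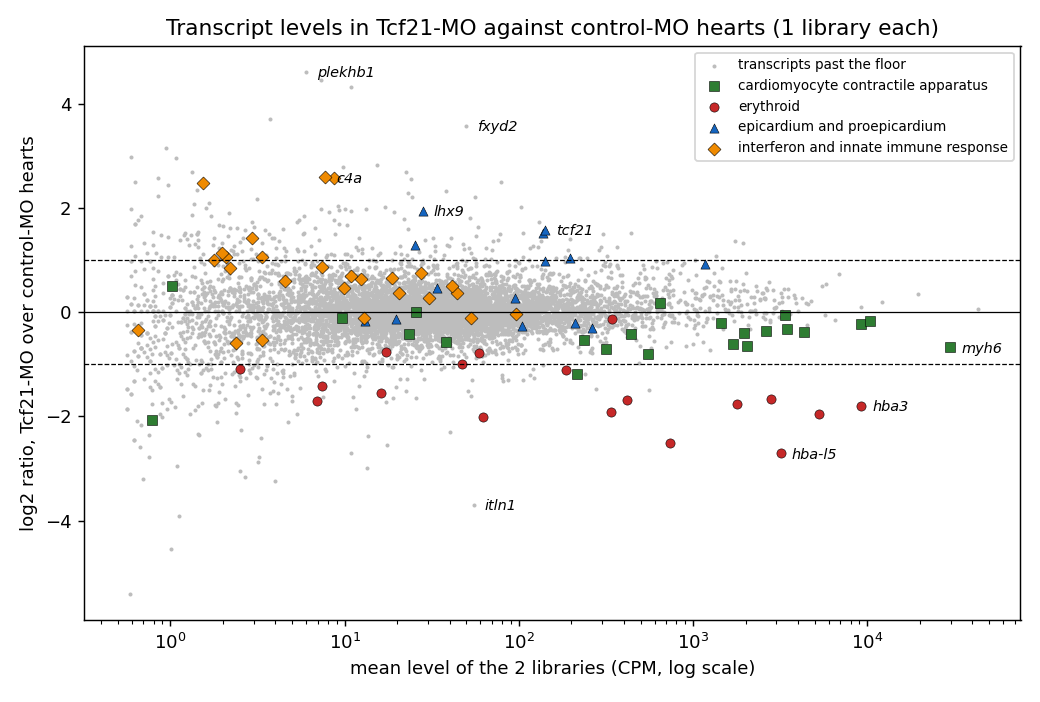
Log2 ratio of Tcf21-MO over control-MO hearts (vertical axis) against the mean level of both libraries in CPM on a log scale (horizontal axis), 1 point per transcript past the floor, with 4 gene lists marked by shape and colour. The dashed lines mark 2-fold, and erythroid members lie below 0 while tcf21 (log2 ratio 1.59) and lhx9 (1.95) lie above the upper line.

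Several epicardial transcripts were higher. Of 14 measured members of the epicardium and proepicardium list, 5 were at least 2-fold higher and 0 lower, and the list median of 0.70 (interval -0.21 to 1.51) lay above those of all 10000 random lists. The transcription factor genes lhx9 and wt1 were 3.87-fold (3.31 to 4.53) and 2.46-fold (2.13 to 2.85) higher, and the other wt1 homeolog was 2.39-fold higher (1.93 to 2.98). The integrin gene itga4 was 2.86-fold higher (2.68 to 3.05) and the keratin gene krt18 2.07-fold (1.97 to 2.18). The retinoic acid synthesis gene aldh1a2, with 1696 and 3310 reads, was 1.99-fold higher (1.87 to 2.11), just under the threshold, and krt8 was 1.91-fold higher (1.87 to 1.95). Ratios were 1.37 for tmem100 (1.22 to 1.54), 1.21 for gata4 (1.13 to 1.29), 0.918 for sema3d (0.789 to 1.07) and 0.890 for upk1b (0.738 to 1.07). The transcripts of gata6, tbx5 and alcam were 1.16-, 1.20- and 1.24-fold lower. Without tcf21, the median of the other 13 members was 0.46 (-0.21 to 1.30). Both intervals reached below 0, with 9 of the 14 members above 0 and 5 below.

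Erythroid transcripts were lower throughout. All 18 measured members of the erythroid list had a log2 ratio below 0, 14 of them at least 2-fold lower, and the list median of -1.67 (-1.92 to -1.08) lay below those of all 10000 random lists. The globin transcript hba-l5 had 98353 reads in the control and 14814 in the Tcf21-MO library, 6.52-fold lower (6.41 to 6.63). The abundant globin hba3 was 3.48-fold lower (3.45 to 3.51) and the carbonic anhydrase gene ca2 5.71-fold lower (5.52 to 5.91). The smallest difference was that of gypc, 1.09-fold lower (1.05 to 1.13), while tal1 was 1.7-fold lower (1.44 to 2.01). The 9 globin rows together took 3.60% of control reads and 0.928% of Tcf21-MO reads. Globin rows resemble each other in sequence and their separate values are uncertain. Among the 15 lowest transcripts of the whole table were also gfi1b, a transcription factor gene of erythroid and megakaryocytic cells, at 8.04-fold lower (6.02 to 10.9), and the Rh blood group gene rhd at 5.85-fold lower (4.67 to 7.39). The thrombocyte list had 3 measured members, too few for a median, of which gp9 was 2.19-fold lower (1.54 to 3.14), while itga2b.2 was 1.03-fold lower and thbs1 had a ratio of 1.11.

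**Figure D2:**
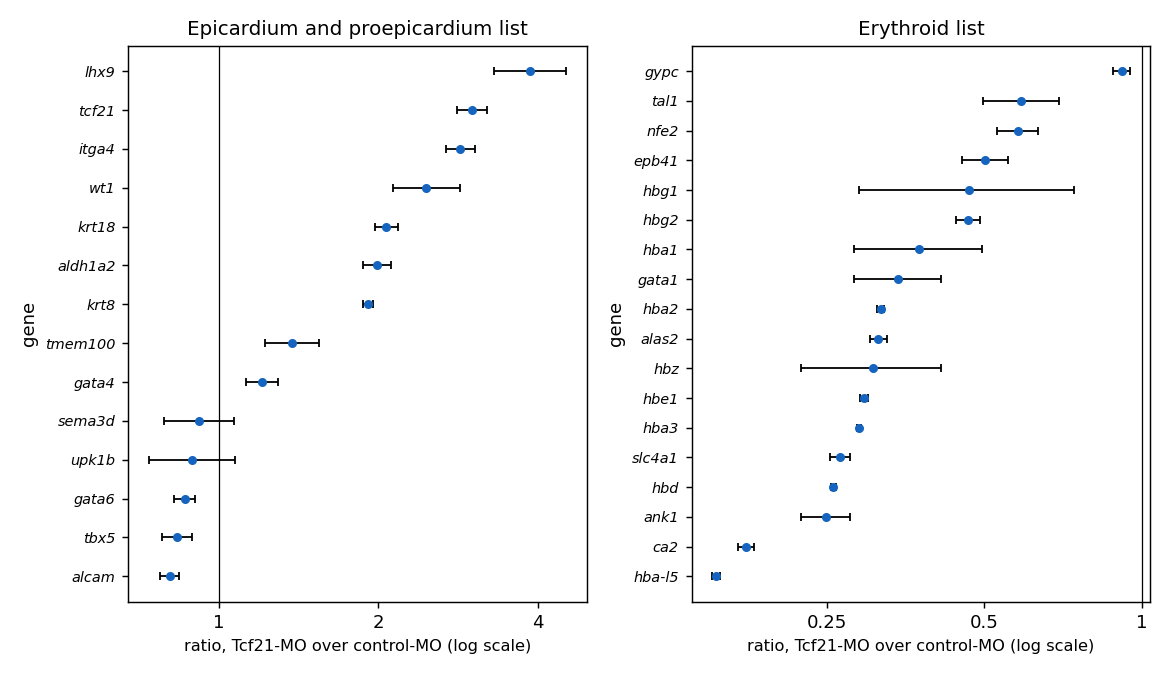
Ratio of Tcf21-MO over control-MO hearts on a log scale (horizontal axis) for each measured member of the epicardium list (left, 14 genes) and the erythroid list (right, 18 genes), with points for the ratio and bars for its 95% counting interval. The vertical line marks a ratio of 1, and epicardial members extend from 0.807 for alcam to 3.87 for lhx9 while all erythroid members lie below 1.

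Contractile transcripts were modestly lower. Of 23 measured members of the contractile apparatus list, 20 had a log2 ratio below 0, 2 were at least 2-fold lower and 0 higher, and the median of -0.41 (-0.62 to -0.21) lay below those of all random lists. The myosin heavy chain gene myh6, among the 5 most abundant transcripts of both libraries, had 657555 and 404343 reads and was 1.60-fold lower (1.59 to 1.60). The nexn transcript was 2.27-fold lower (2.16 to 2.38), and the row listed as myh7, which the name table calls myh15, had 23 and 5 reads. The muscle methyltransferase gene smyd1 was 1.75-fold lower (1.7 to 1.80) and tpm1 was 1.12-fold lower (1.11 to 1.13), whereas csrp3 had a ratio of 1.13 (1.10 to 1.16). In the calcium handling and conduction list, 0 of 8 members passed 2-fold, and the median was -0.28 (-0.68 to 0.58; percentile 0.55). Its lowest members were popdc2 at 1.60-fold and bves at 1.49-fold lower, and its highest were gjc1 and calr, with ratios of 1.49 (1.40 to 1.59) and 1.26 (1.24 to 1.29). The natriuretic peptide list had 5 members with a median of 0.17 (percentile 70.6), and nppb had a ratio of 1.58 (1.54 to 1.63).

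Cardiac transcription factor genes were mixed, with a median of -0.29 (-0.56 to 0.01; percentile 0.02) over 28 members. Of these, 2 were at least 2-fold higher and 3 lower. The T-box gene tbx2 was 4.63-fold higher (4.13 to 5.21) and the Hairy-related gene hey1 2.05-fold higher (1.86 to 2.26). The lower members included irx3, 2.39-fold lower (1.68 to 3.45), and the muscle coactivator gene myocd, with 1138 and 553 reads and a log2 ratio of -1.01.

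Matrix transcripts were higher. In the extracellular matrix list, 4 of 24 members were at least 2-fold higher and 0 lower, with a median of 0.37 (0.14 to 0.82; percentile 99.98). The housekeeping list, with 0 of 16 members past 2-fold, had a median of 0.31 (-0.07 to 0.62), so a median of this size was not particular to matrix genes. The collagen genes col1a2 and col18a1 were 2.57-fold (2.52 to 2.61) and 2.5-fold (2.46 to 2.54) higher, col1a1 2.12-fold and the lysyl oxidase gene loxl2 2.03-fold, while vcan was 1.60-fold lower (1.49 to 1.72). Of 17 matrix remodelling genes, 5 were at least 2-fold higher and 0 lower, with a median of 0.46 (0.23 to 1.26), above all random lists. The collagenase gene mmp1 had 11 reads in the control and 247 in the Tcf21-MO library, 22.9-fold higher (12.6 to 46.4), and mmp13 was 3.94-fold higher (3.0 to 5.23). Higher members also included plat (2.86-fold) and mmp9 (2.40-fold). The adhesion and junction list had 25 members, 1 of them (itga4) at least 2-fold higher, and a median of 0.24 (percentile 99.62).

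The fibroblast and smooth muscle lists had medians inside the central 95% of random lists, with intervals that crossed 0. Of 9 fibroblast genes, 3 were at least 2-fold higher and 0 lower, with a median of 0.23 (-0.49 to 1.36; percentile 91.0). The higher members were tcf21, col1a1 and col1a2, which other lists also hold, while pdgfra was 1.94-fold lower (1.77 to 2.12). In the smooth muscle list, 1 of 7 members was at least 2-fold lower and the median was -0.22 (-1.5 to 0.48; percentile 2.81). That member was the smooth muscle actin gene acta2, with 14657 and 5081 reads, 2.83-fold lower (2.74 to 2.92), a value made uncertain by reads that other actins can share. The epithelial-mesenchymal transition list, which also holds acta2, had 13 members and a median of -0.24 (percentile 0.57), and vim had a ratio of 1.68 (1.66 to 1.71). Of 17 endothelial genes, 0 were higher and 2 lower, lmo2 at 2.30-fold (2.12 to 2.5) and prox1 at 2.12-fold (1.64 to 2.77), and the median of -0.01 lay at percentile 46.0. The valve list had 12 members, 0 past 2-fold, and a median of -0.10 (percentile 15.3).

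Innate immune transcripts were higher. Of 26 members of the interferon and innate immune list, 8 were at least 2-fold higher and 0 lower, with a median of 0.64 (0.37 to 1.01), above all random lists. The complement genes c4a and c3 were 6.11-fold (4.34 to 8.81) and 6.04-fold (4.38 to 8.52) higher, from 39 and 44 control reads, and the cytokine gene il1b had 8 and 46 reads. The intervals of socs1 and rel included 1, while the other socs1 homeolog, with 16 and 60 reads, was 3.82-fold higher (2.17 to 7.10). Of 21 leukocyte and macrophage markers, 4 were at least 2-fold higher and 0 lower, with a median of 0.38 (-0.05 to 0.86; percentile 99.91). The arginase gene arg1 was 3.96-fold higher (2.91 to 5.46) and the oxidase subunit gene ncf4 2.76-fold (1.55 to 5.13), and the others were mmp9 and tyrobp (2.29-fold).

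Lists of markers of other tissues held members in both directions. Of 24 neural and neural crest genes, 9 were at least 2-fold lower and 3 higher, with a median of -0.76 (-1.38 to 0.07), below all random lists. Over members with at least 100 reads the median was 0.00. The neuronal gene stmn2 was 9.74-fold lower (5.50 to 18.8) and the neurofilament gene nefm 4.42-fold lower (2.33 to 9.07), while tubb2b, stmn1 and chga had ratios of 1.58 (1.49 to 1.68), 1.09 (1.01 to 1.17) and 1.00 (0.856 to 1.17). The myelin genes mpz and mbp were 4.08-fold (3.76 to 4.43) and 3.22-fold (2.52 to 4.15) higher. Of 14 epidermal genes, 3 were lower and 0 higher, with a median of -0.37 (-1.03 to 0.54; percentile 0.19). They were grhl3 (2.06-fold), the intelectin gene itln1, the lowest named transcript, with 1822 and 138 reads (13-fold lower, 10.9 to 15.5), and the row listed as otog, which the name table calls otogl2, at 2.45-fold lower (2.28 to 2.63). Of 11 foregut, pancreas and lung genes, 3 were lower and 0 higher, namely sftpc at 3.44-fold (2.30 to 5.26), cela1 at 3.23-fold (1.85 to 5.94) and ctrb1 at 2.35-fold, with a median of -0.68 (-1.66 to 0.03; percentile 1.19). The cartilage list had 9 members, 1 of them (col9a2) at least 2-fold higher at 2.21-fold (1.85 to 2.66), and a median of 0.90 (-0.28 to 1.14), above all random lists. That median was 0.50 with no floor on reads. At 1.5-fold, only 3 of the 9 members were higher with an interval that excluded 1, and 6 passed neither way. The median thus rests partly on members whose intervals included 1. The row listed as lect1, cnmd in the name table, was 1.94-fold higher (1.7 to 2.22). Of 21 liver genes, 3 were higher and 0 lower, with a median of 0.08 (percentile 79.6) that was 0.00 when scaled without the 50 most abundant transcripts. They were c3, fgb (2.86-fold, 2.08 to 4.0) and cyp3a4 (2.03-fold). Of 18 skeletal muscle genes, 2 were lower, eno3 and myog with 25 and 20 control reads, with a median of -0.13 (percentile 7.23), and acta1 was 1.97-fold lower (1.91 to 2.04). The ciliated list had 7 members, 0 past 2-fold, a median of 0.12 (percentile 73.4) and a mean of -0.16. The pronephros list had 4 measured members, too few for a median, of which only wt1, also an epicardial gene, was 2-fold higher.

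**Figure D3:**
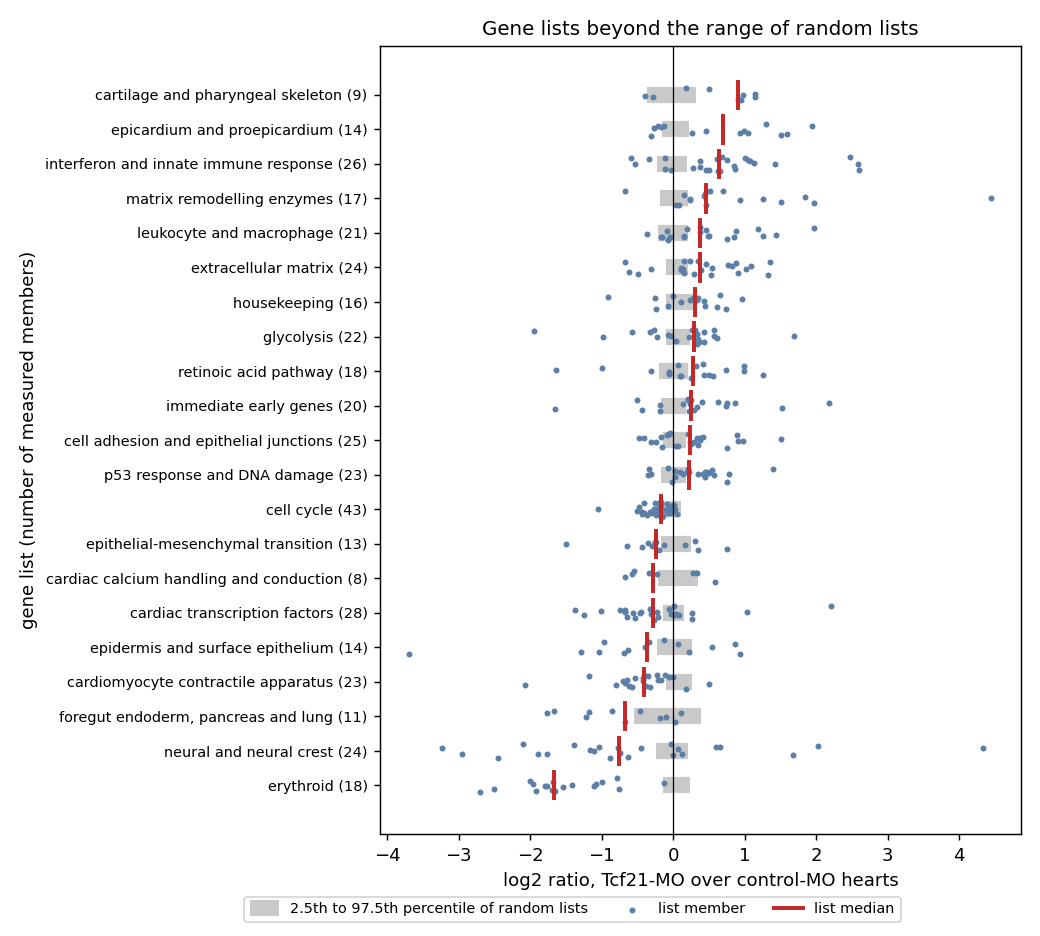
Log2 ratio of Tcf21-MO over control-MO hearts (horizontal axis) for the members of the 21 gene lists whose median lay outside the central 95% of random lists, with dots for members, red lines for medians and grey bars for the random range. The erythroid median (-1.67) and the neural median (-0.76) are the lowest, and the cartilage median (0.90) is the highest.

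The transcripts with the largest ratios lay partly outside these lists. The highest was plekhb1, with 8 and 204 reads, 26-fold higher (12.9 to 61.0), followed by mmp1. The receptor gene gpr84 was 13.8-fold higher (7.04 to 30.9), with 9 and 122 reads, and the sodium pump regulator gene fxyd2 was 12.0-fold higher (10.1 to 14.4), with 137 and 1612 reads. The neuronal pentraxin gene nptx1 was 7.17-fold (5.55 to 9.41), xa-1 6.94-fold (5.05 to 9.76), lcor 6.48-fold (5.28 to 8.01) and the ficolin gene fcn1 5.70-fold (5.14 to 6.34) higher. The row listed as angptl5, which the name table calls angpt4, was 5.88-fold higher (4.86 to 7.17). For unc50, the homeologs differed, with a ratio of 5.06 (4.38 to 5.86) for the S copy and 1.15 (0.954 to 1.38) for the L copy. At the other end, igf3 was 9.38-fold lower (4.72 to 21.2), mmp21 8.73-fold (4.37 to 19.8), cplx1 7.55-fold (4.22 to 14.7), ankrd12 7.08-fold (4.03 to 13.4), traf3ip3 6.60-fold (4.89 to 9.07) and tmod4 5.22-fold (4.08 to 6.74). The carbonic anhydrase gene ca13 was 4.92-fold lower (4.28 to 5.67). Among the most abundant transcripts, the row listed as aifm2 had 751574 and 772581 reads, a ratio of 1.05, and slc25a5 and eef1a1 had ratios of 1.14 and 1.28. Whether the reads of the aifm2 row come from that gene was not checked, and its high level is uncertain.

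Pairs of homeologs gave a check across genes within these libraries. Over 569 pairs with both rows past the floor, the rank correlation of their log2 ratios was 0.51 (Pearson 0.54), where genes are not independent replicates and shared reads raise the value. In 53 pairs at least 1 row passed the 2-fold rule, in 11 of them both rows passed it in the same direction, and in 0 pairs in opposite directions.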

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

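Removal of the length trend, 1 transcript per symbol, and symbols from the name table were alternatives chosen after seeing the data. The log2 ratio of tcf21 stayed between 1.5 and 1.61 in every setting run. Of 187 other named transcripts, 69 passed the 2-fold rule and 0 of those changed sign under any setting, while 7 others did. Counts of 2-fold higher and lower transcripts were 196 and 213 when scaled to the total count, 214 and 196 with DESeq2 size factors, and 180 and 239 when scaled without the 50 most abundant transcripts. The erythroid median ran from -1.75 to -1.64 over the settings. Medians near 0 of the apoptosis, FGF and PDGF, Notch and hedgehog, BMP and TGF-beta, hypoxia, liver and endothelial lists changed sign within their intervals in at least 1 setting. With a floor of 100 reads, 106 transcripts were lower, and the neural median turned from -0.76 to 0.00 (0.000173), because members with few reads were left out. At a threshold of 1.5-fold, 636 were higher and 542 lower, and at 4-fold 33 and 34. Scaling without the 50 most abundant transcripts moved medians beyond their intervals to -0.26 for cell cycle, 0.0909 for oxidative phosphorylation, -0.11 for the tricarboxylic acid cycle and fatty acid oxidation, 0.12 for ribosomal proteins and -0.13 for heat shock, since it shifted the median of all transcripts to -0.08. Removal of the length trend moved oxidative phosphorylation to 0.0835 and ribosomal proteins to 0.0931, a shift whose cause was not tested further. The cartilage median was 0.50 with no floor. Depth limits the transcripts near the floor, where intervals are wide, and not the abundant ones. No paired analysis was possible because each group had 1 library.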

Other observations

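The tests of explanations for the erythroid, epicardial and innate immune differences were chosen after the results were seen.

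Signalling lists were mostly near even. The retinoic acid list had 18 members, 1 higher and 1 lower by 2-fold, with a median of 0.28 (percentile 99.64), rarres1 2.39-fold higher (2.30 to 2.49) and aldh1a1 3.12-fold lower (2.68 to 3.65). The BMP and TGF-beta list had 30 members, 0 past 2-fold, and a median of 0.07 (percentile 82.2) with a mean of 0.00 of the opposite sign, and bmp2 was 1.75-fold lower (1.58 to 1.93). Of 18 FGF and PDGF genes, 1 was higher (fgf9, 3.02-fold, 1.99 to 4.70) and 1 lower (fgf8, 2.76-fold, 2.00 to 3.86), with a median of 0.01 (percentile 58.9) and a mean of -0.01. The Wnt list (35 members, 2 higher, 1 lower) had a median of 0.11 (percentile 93.3), with rspo2 2.19-fold higher (1.35 to 3.64), fzd5 at 5 and 18 reads, and wnt5a 2.16-fold lower (1.53 to 3.10), and the Notch and hedgehog list (16 members, 1 higher, hey1) a median of 0.01 (percentile 55.0).

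Proliferation genes were slightly lower. Of 43 cell cycle genes, 40 were below 0, but only cenpe passed 2-fold (2.08-fold lower, 1.86 to 2.32), and the median was -0.17 (-0.23 to -0.14; percentile 0.11). The DNA damage list had 23 members and a median of 0.23 (percentile 99.35), with ccng1 at 1.71-fold (1.65 to 1.78). Apoptosis genes had 20 members, 0 past 2-fold, and a median of 0.00 (percentile 50.3). Glycolysis genes (22 members, 1 higher, 1 lower) had a median of 0.29 (percentile 99.48), with eno3 at 25 and 6 reads and hk2 3.24-fold higher (2.5 to 4.23), and immediate early genes (20 members, 2 higher, 1 lower) a median of 0.24 (percentile 99.46), with fos 2.89-fold (2.10 to 4.01) and fosl2 4.63-fold (2.83 to 7.94) higher and the row listed as klf4, klf17 in the name table, 3.16-fold lower (2.64 to 3.79). Of 16 housekeeping genes, 0 passed 2-fold and the median was 0.31 (percentile 97.92), with actb at 1.67-fold (1.66 to 1.68). Oxidative phosphorylation (49 members, 0 past 2-fold) and ribosomal protein genes (73 members, 0 past 2-fold) had medians of 0.18 and 0.20 at percentiles 96.3 and 95.1. The tricarboxylic acid cycle and fatty acid oxidation list (33 members, 0 past 2-fold) had a median of -0.02 (percentile 8.08), the heat shock list (28 members, 0 past 2-fold) a median of -0.05 (percentile 9.42) and a mean of 0.01, and the hypoxia list (21 members, 1 lower, cat at 2.28-fold) a median of 0.07 (percentile 71.6).

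The lower erythroid transcripts might reflect less blood in the dissected hearts or fewer or less mature red cells. A loss of blood of every kind would lower leukocyte markers too, but their median was 0.38 (-0.05 to 0.86). Cells resident in the tissue may carry these markers too, so this does not exclude a loss of blood. Thrombocyte markers differed, with gp9 2.19-fold lower, itga2b.2 1.03-fold lower and thbs1 at a ratio of 1.11. A scaling error was argued against by the erythroid median, which was at most -1.67 over 3 scalings and the length correction. A smaller number of red cells of a single kind would lower all globins alike. Over 6 globin rows with at least 1000 reads, the falls ran from 2.15-fold (2.04 to 2.26) to 6.52-fold (6.41 to 6.63). These rows thus did not fall alike within counting error. Their standard deviation of log2 ratios was 0.52, at percentile 81.5 of random sets, but those sets hold unrelated genes and cannot decide the question. With 1 library per group and reads that globins can share, fewer red cells cannot be told apart from a change within red cells. Drainage of blood at dissection and differences between the pools, with 1 library per group, stay open.

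The higher epicardial transcripts, with tcf21 among them, may be worth following up. Stabilisation of the tcf21 transcript by the morpholino was not tested and stays open for tcf21 itself. Carry-over of neighbouring tissue was not decided and stays open. The liver median was near even at 0.0833 (-0.10 to 0.46; percentile 79.6), with 12 members above 0 and 9 below. The cartilage median was 0.90 (-0.28 to 1.14). Both intervals overlapped that of the epicardium list (-0.21 to 1.51), but an unchanged list would overlap it too, so the overlap cannot decide. A larger share of epicardial cells cannot be told apart from higher expression per cell, and 3 of the 14 members (alcam, tbx5 and gata6) had intervals wholly below 1. The cardiac transcription factor list also holds tbx5 and gata6, but it holds gata4 too, which had a ratio of 1.21 (1.13 to 1.29). Members in both directions are shared with other lists, such as itga4 and alcam with the adhesion list.

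The higher innate immune transcripts might come from more leukocytes or from a response in heart cells. The innate median exceeded the leukocyte median by 0.27, their intervals overlapped, and the lists shared 0 genes. Medians of different gene sets cannot separate these explanations, so they cannot be told apart. A DNA damage response to the morpholino was not decided and stays open too. The 20 response genes of the DNA damage list had a median of 0.29 with an interval of 0.10 to 0.47. That interval overlapped the one of the innate list, but an unrelated small shift could overlap it too, so the overlap cannot decide. Other effects of the injected oligomer, and differences in embryo health between the pools, were not tested.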
